A study of Arabidopsis thaliana with 6 samples.

How the data were processed

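Whole-genome bisulfite sequencing measures cytosine methylation, because bisulfite converts unmethylated cytosines to uracil, which is read as T, and leaves methylated cytosines as C. The series held 6 libraries of Arabidopsis thaliana (Columbia) from 2 genotypes and 3 tissues. The genotypes were wild type and ddcc, a quadruple mutant of DRM1, DRM2, CMT2 and CMT3. The tissues were postmature-green-stage seed, dry seed and leaf of 3-week plants, with 1 library per group. Per the labels, 500 ng of DNA was mixed with 3 ng of unmethylated lambda DNA as a conversion control. It then went through 2 bisulfite rounds and 10 PCR cycles, and reads were aligned to TAIR10. The aligner, the caller, the filters and the conversion rate were not given in the sources used here, and no lambda reads were listed, so the conversion rate could not be measured.

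The deposited values were counts: for each cytosine of the 5 nuclear chromosomes and each strand, a count of methylated reads and a count of unmethylated reads. In every library the listed fraction equalled methylated reads over all reads. No listed cytosine had exactly 1 methylated read, and none had fewer than 2 reads. Sites with 1 methylated read had therefore been left out before deposit. Between 3.87 and 12.2% of the cytosines listed in any library were absent from a given library and context. This lowers a level near 0 and raises a high CG level, and the size of the effect was measured with an added setting described here. Contexts and strands of the 6 libraries showed 0 conflicts.

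Read counts summed over cytosines ranged from 1249655790 in wild type postmature-green seed to 1726817750 in ddcc dry seed, and the median depth per cytosine from 33 to 44. A read counts in these sums once for each cytosine it covers, so they are not numbers of reads. Sites with fewer than 4 reads, 0.313 to 1.04% of those listed, were left out. The level of a library in a context (CG, CHG or CHH, where H is any base but G) was the methylated reads divided by all reads at its cytosines, given with a 95% Wilson interval. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. The pericentromere was taken as the DNA within 3 Mb of approximate centromere midpoints, and the rest as arms.

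The comparisons and their tests, the gene lists and the rule for naming genes were fixed before the data were examined. They were ddcc against wild type within each tissue, the 3 tissue pairs within each genotype, and the tissue difference in wild type minus that in ddcc. A difference of levels was given with a 95% block bootstrap interval (blocks of 1 Mb, 2000 draws) and was taken as present where the interval left out 0. These intervals describe variation along the genome between 2 libraries. With 1 library per group there is no replicate check, and no test here compares plants. Any difference in handling between libraries coincides with the groups.

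Windows of 500 bp with at least 4 covered cytosines of a context were compared by a 2-sided Fisher exact test on methylated and unmethylated read counts. Benjamini-Hochberg adjustment ran over all windows of a comparison and context. A window was called at an adjusted p under 0.01 and a difference of at least 40 points for CG, 20 for CHG or 10 for CHH. The same test ran on the bodies and flanks of the 27444 protein-coding genes and of listed genes of any class, with at least 10 covered cytosines in the region. Gene counts include both. Reads that span several cytosines are not independent in this test, so the size threshold carries most of the selection. Levels of windows and genes were taken over sites with at least 4 reads in both libraries of a comparison, so the value of a library can differ between comparisons.

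The gene table was the RefSeq annotation of TAIR10.1, which carried no strand. The planned 1 kb upstream of each gene was therefore replaced by both 1 kb flanks together. Its register against the deposited cytosines was checked at the conserved CG near the ends of tRNA genes and at the starts of protein-coding genes, and both matched on all 5 chromosomes. The class named pseudogenes and transposable element genes held 3917 entries.

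Fixed lists covered seed storage proteins (9 genes), oil body and seed oil (11), seed maturation regulators (12), late embryogenesis abundant proteins (14), leaf photosynthesis (15), DNA methylation machinery (19), imprinted genes demethylated in endosperm (10), silenced loci and transposons (10) and housekeeping (10). All 108 gene IDs matched. The F-box gene SDC and the homeodomain gene FWA are in both the imprinted and the silenced list. Each list's median difference was ranked among 10000 random lists matched on covered cytosines and on pericentromere or arm. These were drawn from the protein-coding genes and the listed genes. Called members were also adjusted over the list alone.

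Genes were named by a fixed rule for ddcc against wild type in each tissue and for dry seed against leaf in wild type. The rule took up to 3 members per list with the largest CHH difference over the flanks. Among called protein-coding genes it also took, in each direction, the 6 largest CHH and 3 largest CHG differences over flanks and the 3 largest CG differences over bodies. The text prints a part of these. The 4 mutated genes were always examined, by depth per cytosine relative to the chromosome median and by stretches without listed cytosines. Members of calls of 5 or fewer, windows named by position and stretches found in a scan of the genome were chosen after their values were seen.

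The settings that were varied were minimums of 1 and 8 reads (the first equals the files' own minimum of 2 reads), sites with at least 4 reads in all 6 libraries, the mean of site levels, an upper limit of 3 times the median depth, subtraction of the CHH level over housekeeping gene bodies, leaving out each chromosome, bootstrap blocks of 100 kb, windows of 200 and 1000 bp, stricter and looser size thresholds, counts divided by 4, flanks of 500 bp and 2 kb, and a pericentromere of 2 Mb to each side. A further setting was chosen after the data were seen. It restored absent sites that had same-strand listed neighbours within 30 bp with at least 10 reads each, as sites with 1 methylated read at the neighbours' mean depth.

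The pooled CG difference between wild type seed and leaf was also split, on sites with at least 4 reads in both libraries. The first part was the difference of levels within sites, weighted by the mean share of reads at each site, and the second was the difference in how reads were spread over sites. This split was chosen after the data were seen.

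The calls, the bootstrap, the split and the restoration were tested on simulated data. Windows and gene bodies with a planted difference were recovered in 99.5 to 100% of 200 cases per size and context, with 0 in the wrong direction and 0 unchanged units called. Planted sizes were 60 and 100 points for CG, 30 and 50 for CHG, and 15 and 25 for CHH, all above the call thresholds. Counts were drawn as independent reads from the same leaf levels in both libraries. The 0 unchanged units called therefore give no rate of false calls for the real data. Bootstrap intervals held the true difference in 95 and 97.7% of 300 simulations. With seed counts drawn from the leaf site levels at the seed depths, the part within sites was 0.000617 points for postmature-green seed and 0.00230 for dry seed against a true value of 0, and both intervals included 0. A simulated level of 0.1% was 0.00515% as listed and 0.0975% after restoration. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.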

Results

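DNA methylation at single cytosines was profiled in postmature-green-stage seed, dry seed and leaf of wild type and ddcc Arabidopsis plants, with 1 library for each of the 6 combinations. DRM1 and DRM2 are methyltransferases of RNA-directed DNA methylation, and CMT2 and CMT3 are chromomethylases that act in CHH and CHG contexts. Read counts summed over cytosines, which count a read once for each cytosine it covers, described the size of the libraries. In wild type they were 1249655790 (postmature-green seed), 1629784120 (dry seed) and 1399318213 (leaf), at median depths of 33, 42 and 35 per cytosine. In ddcc these sums were 1323783145, 1726817750 and 1345384814 in the same order, at median depths of 35, 44 and 33. Between 36887920 and 39887979 cytosines were listed per library. No group had a replicate, so no value carries a replicate error.

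The 4 mutated genes were examined first, as a check of the genotype labels. DRM1 (AT5G15380) lacked reads over most of its length in all 3 ddcc libraries and in no wild type library. Its depth relative to the chromosome median was 0.253 in ddcc postmature-green seed, 0.247 in ddcc dry seed and 0.262 in ddcc leaf, against 1.07, 1.03 and 1.10 in wild type. The missing stretch ran on TAIR10 chromosome 5 from 4983978 to 4994044, a length of 10067 bp with 3687 cytosines. It also covered AT5G15340, ENODL17, AT5G15360 and AT5G02405. In wild type, 3256 (postmature-green seed), 3388 (dry seed) and 3504 (leaf) of these cytosines were listed. CMT2 (AT4G19020) had a short gap of 21 cytosines in the ddcc libraries, on chromosome 4 from 10416297 to 10416342. CMT3 (AT1G69770) and DRM2 (AT5G14620) had no shared gap beyond 1 and 3 cytosines. Relative depth over these last 3 genes was 0.951 to 1.10 in all 6 libraries. The stretch and the gap split the libraries by genotype as labelled, for DRM1 and CMT2; the deposited values carry no such mark for CMT3 and DRM2.

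**Figure D1:**
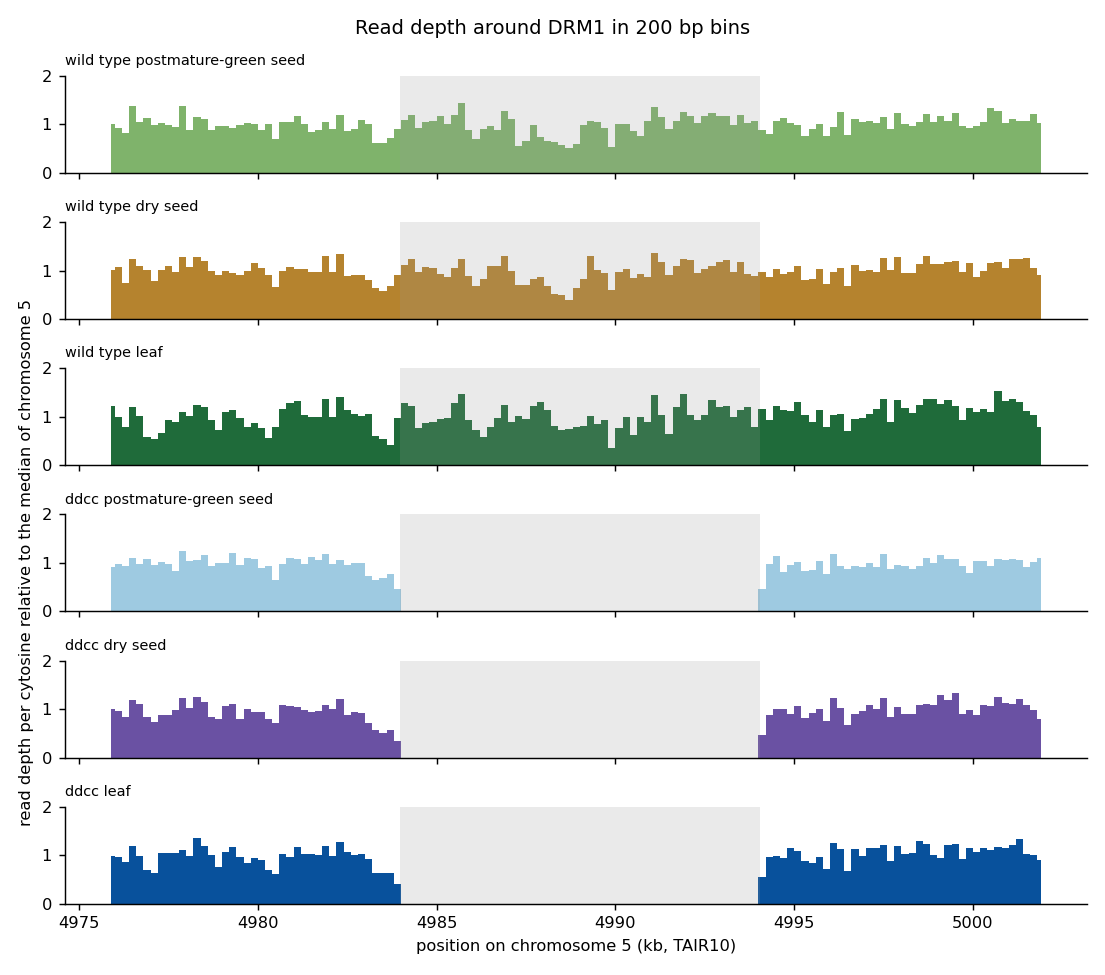
Read depth per cytosine around DRM1 in 200 bp bins, relative to the chromosome 5 median, against position on chromosome 5, with 1 panel for each of the 6 libraries. The grey stretch from 4983978 to 4994044 held no listed cytosine in any of the 3 ddcc libraries and was covered in the 3 wild type libraries.

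The comparison of ddcc with wild type asks how much of the methylation in each tissue depends on the 4 enzymes. Nearly all CHG and CHH methylation was gone in ddcc in both seed stages and in leaf. The CHH level fell from 2.72% in wild type to 0.0675% in ddcc in postmature-green seed, from 2.87 to 0.0174% in dry seed and from 1.55 to 0.0127% in leaf. The differences were -2.65 points (95% bootstrap interval -3.53 to -1.91), -2.85 points (-3.76 to -2.08) and -1.54 points (-2.01 to -1.13). CHG levels fell from 8.5 to 0.108%, from 8.49 to 0.0618% and from 7.75 to 0.0225% in the same order, by -8.39 points (-11.2 to -6.00), -8.43 points (-11.2 to -6.07) and -7.73 points (-10.1 to -5.73). The Wilson intervals of single levels were narrow, such as 7.75 to 7.76% for CHG in wild type leaf and 0.0173 to 0.0174% for CHH in ddcc dry seed.

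The ddcc levels near 0 are low estimates, because sites with 1 methylated read are absent from the files. With such sites restored, the ddcc CHH level was 0.322% in postmature-green seed, 0.122% in dry seed and 0.109% in leaf, and the CHG level was 0.380, 0.195 and 0.136%. As a background, the CHH level over the bodies of the 10 housekeeping genes was taken as listed, without restoration. It was 0.0366% in wild type postmature-green seed, 0.00763% in wild type dry seed and 0.00369% in wild type leaf. In ddcc it was 0.0531, 0.00710 and 0.00614% in the same order. These background values are not on the scale of the restored levels. Restored ddcc CHH in arms alone was 0.315, 0.116 and 0.104%, close to the restored level over the whole genome. Because sites with 1 methylated read are absent, a gene value of 0 in ddcc is a listed value of 0 and sets no upper limit.

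CG methylation stayed near the wild type level, and its pooled difference changed direction between tissues. It was 27.3% in ddcc against 24.96% in wild type in postmature-green seed, a difference of 2.34 points (1.64 to 2.91). In dry seed it was 27.1 against 25.9%, a difference of 1.18 points (0.469 to 1.73). In leaf it was 26.7 against 28.5%, a difference of -1.79 points (-2.83 to -0.994). When sites rather than reads were weighted equally, the differences shrank to 0.580 points in postmature-green seed (0.439 to 0.698), 0.0581 points in dry seed with an interval that included 0, and -0.147 points in leaf (-0.296 to -0.00860). Read depth was uneven in the same libraries, since the depth in the pericentromere relative to arms was 0.913 in both wild type seed libraries and 0.995 to 1.03 in the other 4.

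**Figure D2:**
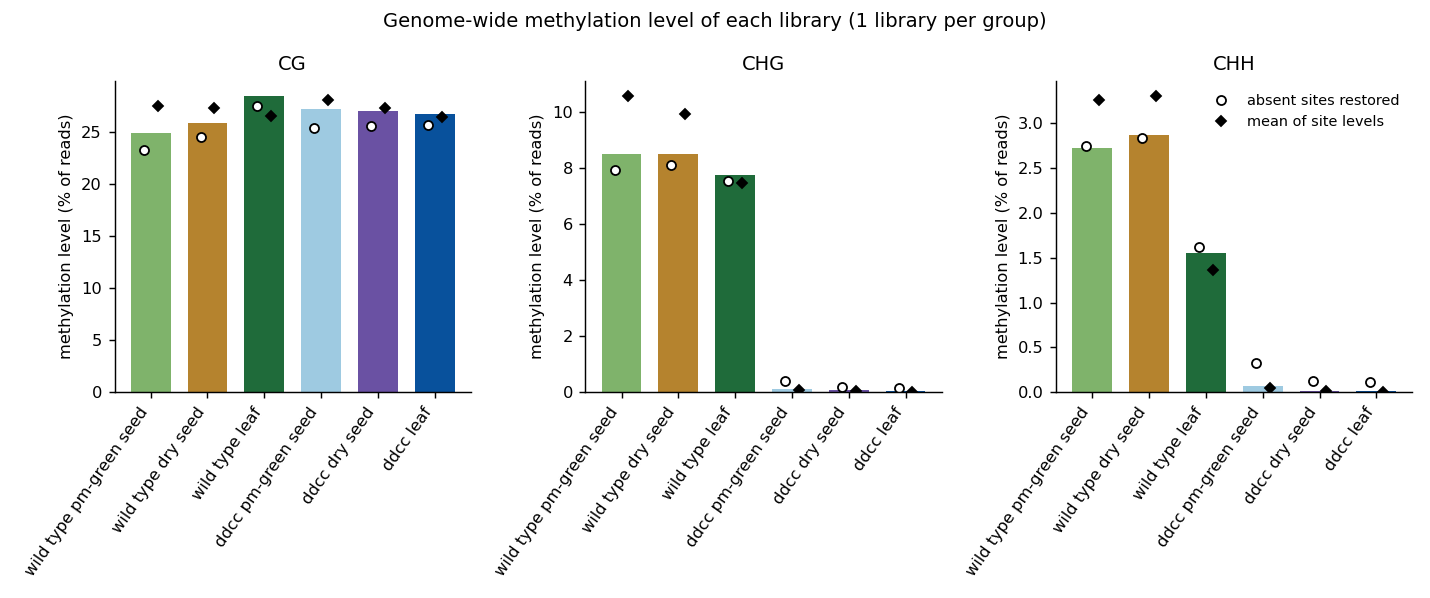
Methylation level in percent in CG, CHG and CHH contexts for the 6 libraries, with bars for the level over pooled reads, open circles for the level with absent sites restored and diamonds for the mean of site levels. CHH reached 2.72 and 2.87% in the wild type seed libraries and 1.55% in wild type leaf, and it was at most 0.0675% over pooled reads in ddcc.

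In windows, CHG and CHH methylation was only lost. CHG was lower in ddcc in 43540 windows in postmature-green seed, 43780 in dry seed and 39509 in leaf, and CHH was lower in 43343, 44295 and 14317. No window was higher in ddcc in either context. At a threshold of 5 points CHH was lower in 49634, 50601 and 32579 windows, so the 10-point threshold limited the leaf count most. The CHH windows called at 10 points were 18.5, 18.9 and 6.10% of the windows tested. They lay mainly near the centromeres, with 80.4% (postmature-green seed), 79.7% (dry seed) and 73.6% (leaf) in the pericentromere against 24.5% of tested windows. Pseudogenes and transposable element genes held 38.2, 37.5 and 53.6% of them against 7.69% of tested windows. Their median CHH level was 17.9, 18.1 and 12.4% in wild type and 0 in ddcc. Called in all 3 tissues were 37666 windows for CHG and 14219 for CHH.

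CG calls were far fewer and went both ways. CG was lower in ddcc in 953 windows in postmature-green seed, 822 in dry seed and 1379 in leaf, and higher in 268, 217 and 241. The balance of the 2 directions depended on the size threshold, since at 20 points 4053, 4080 and 4990 windows were lower and 4091, 3441 and 2701 were higher. Of the calls at 40 points, 509 were lower and 100 were higher in all 3 tissues. The 509 recurrent losses had median CG levels of 80.7% in wild type dry seed and 18.4% in ddcc dry seed, and 46.0% lay in the pericentromere. The 100 recurrent gains had median CG levels of 4.65% in wild type dry seed and 65.7% in ddcc dry seed, and 52% lay in protein-coding genes, against 55.2 to 55.3% of tested windows. Examples of losses, chosen after their values were seen, were chromosome 2 from 2870001 to 2870500 in AT2G06960 (0.510% in ddcc and 93.3% in wild type dry seed) and chromosome 5 from 7057001 to 7057500 over MIR8167d (0.506 and 87.6%). Examples of gains were chromosome 3 from 12799001 to 12799500 (83.7 and 0%) and chromosome 1 from 21069501 to 21070000 (79.1 and 1.16%).

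At the protein-coding and listed genes, losses of non-CG methylation past the size thresholds were called at a minority of the genes tested. CHH over the flanks was lower in ddcc at 798 genes in postmature-green seed, 879 in dry seed and 132 in leaf. CHH over bodies was lower at 902, 916 and 195 genes. With absent sites restored these counts came to 677, 775 and 81 for flanks and 807, 835 and 138 for bodies. CHG was lower over the flanks of 1273, 1306 and 1362 genes and over the bodies of 1012, 1028 and 948 genes. No gene was higher in ddcc in either context. The genes tested for CHH over flanks numbered 27320 in postmature-green seed, 27321 in dry seed and 27319 in leaf.

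In dry seed the largest losses of flanking CHH methylation were at AT1G23915 (0% in ddcc and 36.2% in wild type), AT4G19270 (0.0828 and 32.6%), AT3G28120 (0.0300 and 30.01%) and AT1G59930 (0.0165 and 28.1%). RKF2 (AT1G19090), a receptor-like kinase gene, fell from 30.1 to 0.0125% over 367 cytosines, and KLCR1 (AT4G10840), a kinesin light chain-related gene, from 28.5 to 0.0280%. In postmature-green seed AT4G19270 (0 and 30.5%), AT3G28120 (0.1003 and 29.9%), RKF2 (0.107 and 28.4%) and AT1G23915 (0 and 28.2%) had the largest losses. In leaf they were AT1G23915 (0 and 19.7%), AT5G39775 (0 and 18.6%), AT3G44580 (0.0129 and 18.0%) and RKF2 (0.0154 and 18.0%). For CHG over flanks, AT4G16015 had the largest loss in all 3 tissues, from 86.5% in postmature-green seed, 81.6% in dry seed and 70.2% in leaf to 0. The chloride channel gene CLC-D (AT5G26240) fell from 71.6 to 0.118% in dry seed and from 65.9 to 0.126% in leaf.

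CG over gene bodies was lower in ddcc at 28 genes in postmature-green seed, 24 in dry seed and 29 in leaf. AT1G64795 had the largest loss in each tissue, with 86.1, 84.4 and 91.5% in wild type and 0 in ddcc. AT3G28922 was at 75.8, 73.5 and 87.6% in wild type and at 7.18, 4.29 and 4.21% in ddcc. Gains were called at 3 genes in postmature-green seed, namely AT4G27360, AT5G47300 and AGL85 (AT1G54760). In dry seed 4 genes gained, namely AT4G27360, AT5G47300, AT3G29560 and AT2G07640. In leaf 2 genes gained, AT5G47300 and AT3G29560. AT5G47300 rose from 7.71 to 56.9%, from 8.86 to 58.6% and from 7.84 to 62.4% in postmature-green seed, dry seed and leaf. AT2G07640 rose from 17.5 to 61.2% in dry seed. CG over flanks was lower in ddcc at 3 genes in postmature-green seed (AT3G29645, AT4G32370 and AT5G19100), at 6 in dry seed and at 12 in leaf.

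Among the fixed lists, the loss was concentrated in the silenced loci and transposons. CHH over flanks was lower in ddcc at 6 of 10 members in postmature-green seed, 7 in dry seed and 2 in leaf. The median difference was -13.6, -15.1 and -4.17 points in the same order, at the 0.01, 0 and 0.01 percentiles of the random lists. The random lists held almost only protein-coding genes, while this list was chosen as silenced loci and transposons. Its percentiles therefore do not compare it with other transposons. CHG over flanks was lower at 7, 8 and 7 members. AT2G15810 fell from 26.4 to 0.0450% in postmature-green seed, from 26.1 to 0% in dry seed (499 cytosines) and from 14.8 to 0% in leaf. AT4G08680 was at 21.5% in wild type and 0 in ddcc dry seed, and AT1G37110 at 20.5 and 0.0133%. The 2 members called in leaf were AT2G15810 and AT1G37110.

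The imprinted genes were mixed. CHH over flanks was lower in ddcc at 2 of 10 members in postmature-green seed and in dry seed and at 0 in leaf, with median differences of -1.36, -1.71 and -0.195 points (percentiles 14.6, 19.6 and 23.8). Both called members were the same in the seed stages, AGL36 (AT5G26650), a MADS-box gene, with 17.6 and 17.4% in wild type seeds, and HDG9 (AT5G17320), a homeodomain gene, with 11.98 and 14.0%. SDC (AT2G17690) was at 6.07% in wild type postmature-green seed and 7.32% in dry seed and was not called at the 10-point threshold.

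For the genes of seed filling and of leaf photosynthesis, the list medians of flanking CHH were near 0, while single members had more. No member of the seed storage, oil, maturation regulator, late embryogenesis abundant, photosynthesis, methylation machinery or housekeeping lists was called in CG, CHG or CHH in any tissue, except that CHG over the flanks of ATS1 (AT4G26740), a caleosin gene of oil bodies, was at 20.7% in wild type leaf and 0 in ddcc leaf. The median CHH differences over flanks in dry seed were 0.000963 points for seed storage proteins (percentile 97.8), -0.0110 for oil (27), -0.175 for maturation regulators (3.4), -0.0193 for late embryogenesis abundant proteins (2.31), -0.0178 for photosynthesis (17.2), -0.0203 for methylation machinery (42.6) and 0.00232 for housekeeping (92.2). The housekeeping mean was -0.139 points, opposite in sign to its median. All these medians are near the level that the absent sites can shift. For all lists, the calls adjusted over the list alone equalled those over all genes.

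Single members of these lists lost smaller amounts, below the 10-point threshold. LEC2 (AT1G28300), a B3 transcription factor of seed maturation, had a flanking CHH level of 3.55% in wild type and 0.0112% in ddcc dry seed (Fisher exact test, adjusted p 5.81e-184 over all genes, 1 library each). DPBF2 (AT3G44460), a bZIP factor, was at 3.63 and 0%, and FUS3 (AT3G26790), another B3 factor, at 1.66 and 0%. SUVH9 (AT4G13460), a SET-domain protein of RNA-directed DNA methylation, was at 6.69 and 0%, and NRPD1A (AT1G63020), the largest subunit of RNA polymerase IV, at 4.78 and 0.0152%. LHCB2.1 (AT2G05100), a chlorophyll a/b-binding protein gene, was at 6.23 and 0.0143%. The largest difference among seed storage genes in dry seed was at SESA3 (AT4G27160), with 0.0257% in ddcc and 0% in wild type.

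**Figure D3:**
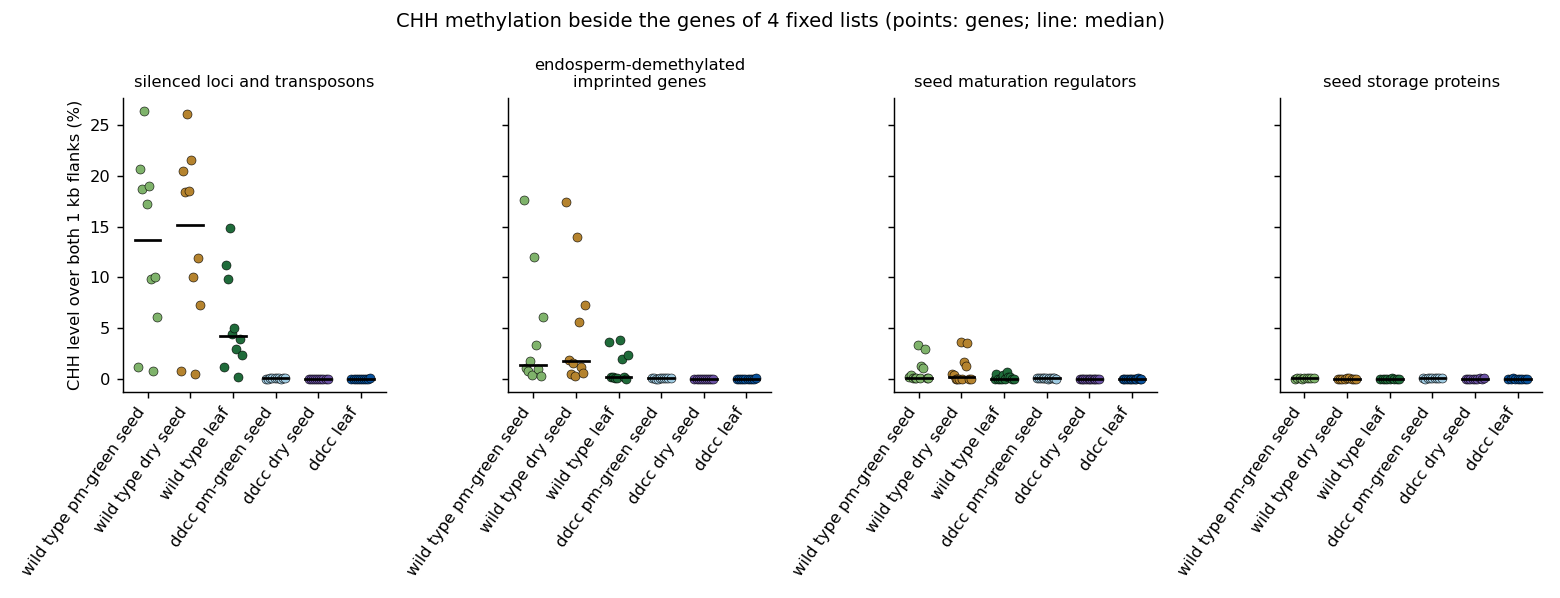
CHH methylation level in percent over both 1 kb flanks of each gene of 4 fixed lists in the 6 libraries, with a point per gene and a line at the median. The silenced loci had medians of 15.2% in wild type and 0% in ddcc dry seed, and the seed storage genes stayed near 0 in all 6 libraries.

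The comparison of seed with leaf in wild type asks how methylation differs between tissues when the enzymes are present. Over the whole genome, non-CG methylation was higher in both seed stages than in leaf. The CHH level was 1.75-fold that of leaf in postmature-green seed, a difference of 1.17 points (0.817 to 1.57). In dry seed it was 1.85-fold, a difference of 1.32 points (0.942 to 1.76). CHG was higher by 0.747 points (0.318 to 1.28) and 0.739 points (0.347 to 1.21). The size of the CHG difference depended on the sites used, since in postmature-green seed it was 0.329 points with an interval that included 0 on sites covered in all 6 libraries and 3.11 points as a mean of site levels. The gain was largest in the pericentromere, where CHH was 10.0% in postmature-green seed, 10.5% in dry seed and 5.18% in leaf and CHG was 32.7, 32.6 and 26.8%. In arms CHH was 0.664, 0.709 and 0.396%, while CHG was 1.79, 1.82 and 1.92%. The pooled CHG level in arms was thus lower in seeds than in leaf, opposite to the whole genome.

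In windows, CHH was higher than in leaf in 20854 windows in postmature-green seed and 22680 in dry seed. It was lower in 4 and 1, and the window on chromosome 1 from 8812501 to 8813000, over AT1G25097 and AT1G25098, was lower in both stages. The other 3 were on chromosome 3 from 1969001 to 1969500 (AT3G06435), chromosome 4 from 3212001 to 3212500 and chromosome 5 from 9189001 to 9189500 (CLC-D). CHG was higher in 7555 and 4954 windows and lower in 174 and 231. With counts divided by 4, these were 4064 and 2763 higher and 68 and 104 lower. Of the dry seed CHH windows, 74.6% lay in the pericentromere, and 48.9% lay between genes against 16.4% of tested windows. Their median level was 21.6% in dry seed and 7.87% in leaf. Of the 4954 CHG windows of dry seed, 3936 (79.5%) were also higher in CHH.

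The seed stages shared 17839 of the 20851 and 22674 CHH windows that were testable in both comparisons. Lists drawn independently would share 2016. Simulated libraries without any difference shared 0, but the simulation called 0 windows in each comparison, so it says nothing about the leaf library that both comparisons use. Part of the excess may come from that library.

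**Figure D4:**
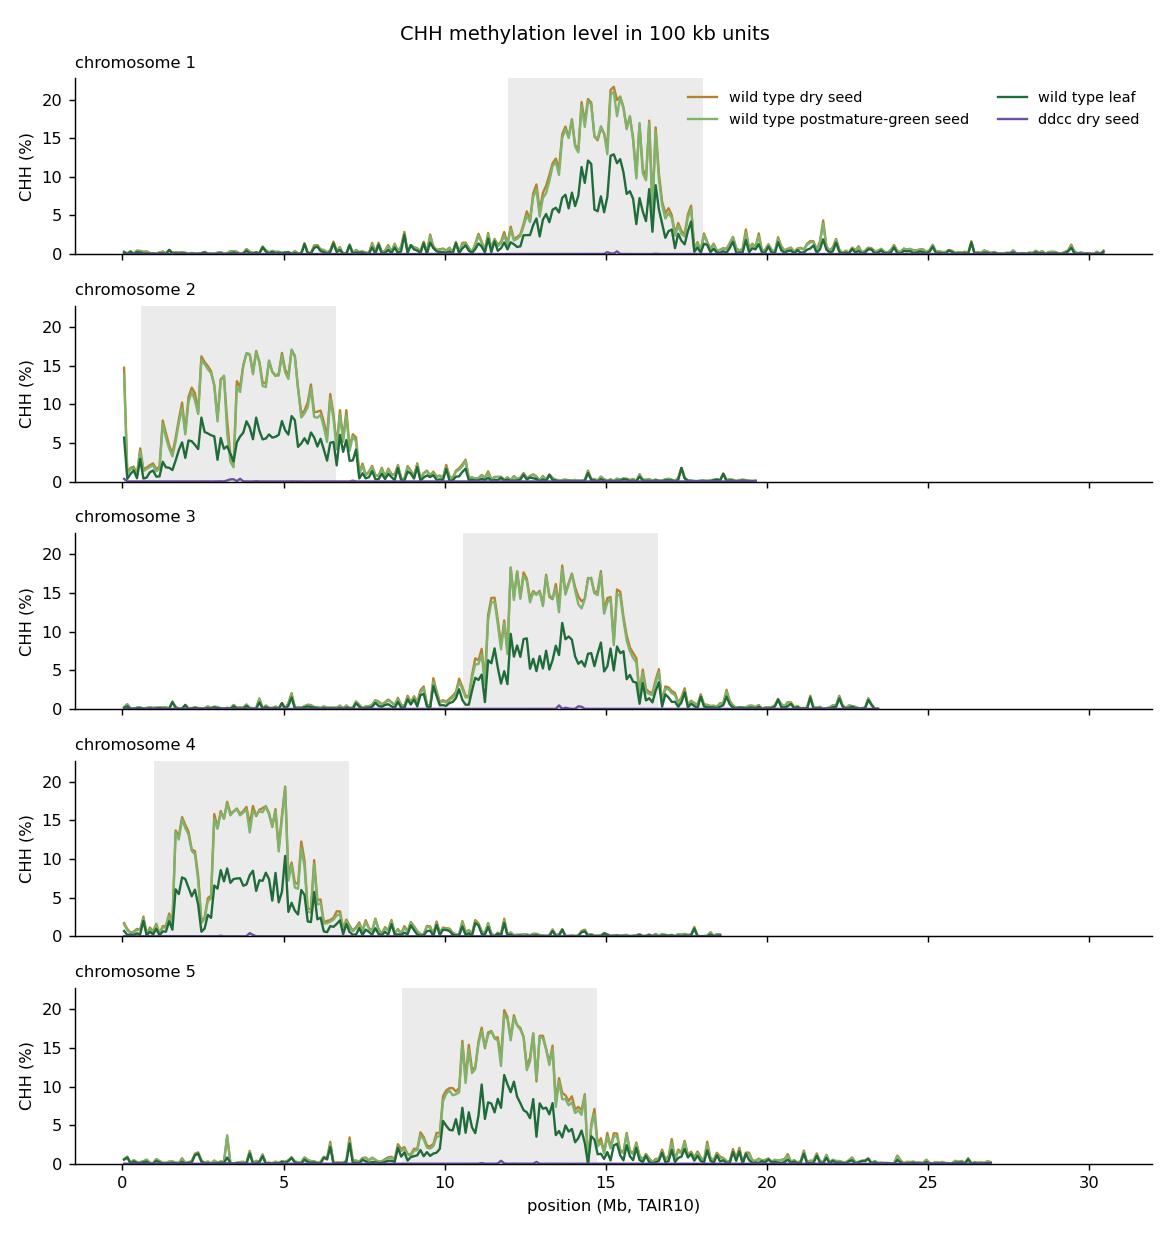
CHH methylation level in percent in 100 kb units along the 5 chromosomes (position in Mb), with lines for wild type dry seed, postmature-green seed and leaf and for ddcc dry seed, and grey for the DNA within 3 Mb of the centromere midpoints. Wild type seeds exceeded leaf in the pericentromere, at 10.0 and 10.5 against 5.18%, and ddcc dry seed was at 0.0386% there.

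CG over pooled reads was lower in wild type seeds than in leaf, by -3.57 points in postmature-green seed (-4.00 to -3.11) and -2.64 points in dry seed (-2.96 to -2.32). This result depended on how sites were weighted, because the mean of site levels put seeds higher by 0.913 and 0.707 points. Few windows changed by 40 points. CG was lower in 196 windows in each seed stage. It was higher in 1 window in postmature-green seed, on chromosome 3 from 16526501 to 16527000 in LOX2. In dry seed it was higher there and on chromosome 1 from 16859001 to 16859500. Of the 196 windows lower in dry seed, 53.6% lay within 1 kb of a protein-coding gene and 1.53% in pseudogenes or transposable element genes. Their median CG level was 29.5% in dry seed and 74.5% in leaf.

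At genes, CHH over flanks was higher than in leaf at 298 genes in postmature-green seed and 320 in dry seed, CHH over bodies at 428 and 426, and none was lower. With absent sites restored these counts were 192 and 226 for flanks and 278 and 290 for bodies. In dry seed the largest differences over flanks were at AT4G19270 (32.6% against 8.63% in leaf), AT1G59930 (29.6 and 6.81%), AT5G27606 (26.9 and 5.06%) and AT1G35215 (29.0 and 7.24%). CHG over flanks was higher at 59 and 30 genes, such as AT4G00005 in dry seed (64.6 and 36.2%). It was lower in dry seed at 7 genes, such as CID12 (AT4G10610; 16.6 and 40.03%) and AT5G44410 (17.5 and 39.9%, but not with 500 bp flanks, where the difference was 0.583 points). In postmature-green seed it was lower at 5 genes, namely VLN2, AT3G07110, ANL2, CID12 and AT4G34070. CHG over bodies was higher at 85 genes in postmature-green seed and at 41 in dry seed. It was lower at AT3G49230 in postmature-green seed and at 4 genes in dry seed (AT1G21928, AT3G54730, AT4G08485 and AT5G06630). CG over bodies was lower in dry seed at 5 genes, namely AT2G03823 (36.7 and 88.2%), AT1G21835 (38.7 and 83.2%), AT2G24880 (34.9 and 78.7%), AT4G14276 and AT5G06630. In postmature-green seed it was lower at 4, namely AT1G21835, AT1G21928, AT2G03823 and AT2G24880.

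Of the lists, the silenced loci stood apart again. CHH over flanks was higher than in leaf at 3 of 10 members in postmature-green seed and at 4 in dry seed, where the list median was 15.6% against 4.52% in leaf. The median difference in dry seed was 8.62 points (percentile 100), against 1.46 points for the random lists, which held almost only protein-coding genes. The 4 members of dry seed were AT4G08680 (22.2 and 5.96%), AT4G03650 (18.7 and 4.78%), AT2G15810 (28.4 and 16.6%) and AT2G12210 (21.2 and 10.7%), and the first 3 were also called in postmature-green seed. AGL36 (16.4 and 4.16% in dry seed and leaf) was the only imprinted gene called in either stage, and the median of that list differed by 1.17 points in dry seed (percentile 92.0). In the other lists 0 members were called for CHH flanks in either stage. Their dry seed medians differed by 0.0110 points for seed storage proteins (39.2), 0.0201 for oil (80.2), 0.00450 for maturation regulators (10.4), 0.0188 for late embryogenesis abundant proteins (98.0), 0.0312 for photosynthesis (99.0), 0.0203 for methylation machinery (77.3) and 0.00468 for housekeeping (35.1). Below the threshold, LEC2 was at 2.93% in dry seed and 0.147% in leaf, DPBF2 at 2.79 and 0.336%, and NRPD1A at 3.09 and 0.0238%. These dry seed values differ from those given against ddcc because each comparison used the sites covered in both of its libraries.

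The comparison of dry seed with postmature-green seed asks what differs between the 2 seed stages. In wild type the pooled levels were close. CHH was higher in dry seed by 0.149 points (0.113 to 0.189), or 1.05-fold, and CG by 0.928 points (0.734 to 1.16). As a mean of site levels CHH was higher by 0.0519 points, but CG was lower, by -0.206 points, and so was CHG, by -0.639 points (-0.792 to -0.494). With absent sites restored the CHH difference was 0.0927 points, and in arms it was reversed, at -0.0813 points. The housekeeping CHH background was higher in the postmature-green seed libraries (0.0366% in wild type, 0.0531% in ddcc) than in the other libraries (0.00369 to 0.00763%). Stage and handling of the libraries cannot be told apart for differences this small. CHG differed by -0.00779 points with an interval that included 0 (-0.0963 to 0.0540). It was higher in dry seed by 0.291 points (0.191 to 0.380) on sites covered in all 6 libraries and by 0.174 points (0.0912 to 0.256) with absent sites restored, so its direction depended on the sites and weights used. CHH was higher in dry seed in 88 windows, of which 42.0% lay within 1 kb of a protein-coding gene, with medians of 41.3 and 28.7%. It was lower in 4 windows, starting at 10526501 and 13979001 on chromosome 1, 14174501 on chromosome 3 and 7057501 on chromosome 5. CHG was lower in 5 windows, starting at 1898001, 11409001 and 17546001 on chromosome 2, 12268001 on chromosome 3 and 11092001 on chromosome 4. With counts divided by 4, these calls came down to 0 higher and 1 lower for CHH and 0 for CHG. No CG window, no gene and no list member was called.

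The same tissue pairs in ddcc ask which tissue differences exist without the 4 enzymes. No CHG or CHH window and no CHG or CHH gene was called between any pair of ddcc libraries, but levels this low leave almost no room for a difference of 20 or 10 points. The CHG level was higher than in leaf by 0.0855 points in postmature-green seed (0.0661 to 0.114) and 0.0393 points in dry seed (0.0232 to 0.0625), or 4.80-fold and 2.75-fold. The CHH level was higher by 0.0548 points (0.0495 to 0.0614) and 0.00465 points (0.00389 to 0.00600), or 5.31-fold and 1.37-fold. These sizes depended on the sites left out of the files. With absent sites restored, the CHG differences were 0.244 and 0.0589 points (2.79-fold and 1.43-fold) and the CHH differences 0.213 and 0.0131 points (2.95-fold and 1.12-fold). Dry seed differed from postmature-green seed by -0.0463 points for CHG and -0.0501 points for CHH, and by -0.185 and -0.200 points with absent sites restored. With the housekeeping CHH level subtracted, both differences between the seed stages had intervals that included 0, and the excess of postmature-green seed over leaf came down to 0.0386 points for CHG and 0.00785 points for CHH. The CG level was higher than in leaf by 0.564 points in postmature-green seed (0.271 to 0.897) and by 0.331 points in dry seed (0.102 to 0.592), and dry seed differed from postmature-green seed by -0.233 points (-0.323 to -0.131). These 3 differences reversed when only sites covered in all 6 libraries were used. CG was lower than in leaf in 49 windows in postmature-green seed and 22 in dry seed, and higher in 10 and 13. At 60 points 3 and 1 were lower and 0 higher, and at 20 points 961 and 657 were lower and 473 and 418 higher. EPR1 (AT2G27380) was lower in gene body CG in both stages, with 29.4% against 79.2% and 35.96% against 78.0%, and AT5G28410 in postmature-green seed, with 33.7 against 79.3%.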

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

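The tests of uneven coverage, of the sites left out before deposit, of the split of the CG difference, of chromosome arms alone, of incomplete conversion alone, of CCG sites, of CAG and CTG sites outside dry seed and of the stretch at DRM1 were chosen only after the results were seen. The tests of CCG sites and of CAG and CTG sites were written as 1 test and split afterwards. The other tests of this part were written before their results, and the departures from them are stated with each.

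The difference between tissues in wild type departed from the same difference in ddcc for 8 levels, by the block bootstrap on the 4 libraries of each comparison. These are differences between groups, with 1 library in each. For CG the wild type difference minus the ddcc difference was -4.13 points between postmature-green seed and leaf (-4.75 to -3.51), -2.97 between dry seed and leaf (-3.42 to -2.55) and 1.16 between dry and postmature-green seed (0.897 to 1.46). With the mean of site levels these 3 shrank to -0.727 (-0.784 to -0.671), -0.205 (-0.308 to -0.0868) and 0.522 (0.406 to 0.652). For CHG it was 0.662 points between postmature-green seed and leaf (0.248 to 1.17) and 0.70 between dry seed and leaf (0.323 to 1.15). The first of these lost its call on sites covered in all 6 libraries, at 0.244 points (-0.121 to 0.750), and with absent sites restored, at 0.148 (-0.132 to 0.532). With the mean of site levels the 2 rose to 3.05 (2.23 to 3.99) and 2.45 (1.76 to 3.24). For CHH it was 1.11 points between postmature-green seed and leaf (0.767 to 1.51), 1.31 between dry seed and leaf (0.938 to 1.75) and 0.199 between dry and postmature-green seed (0.162 to 0.240). The listed CHG and CHH levels of ddcc were near 0. The values between seed and leaf in these contexts therefore largely repeat the wild type differences and are not separate results.

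The lower pooled CG level of wild type seeds against wild type leaf was weighed first. The sites left out before deposit do not account for it, since with them restored the dry seed difference was -2.94 points, and uneven coverage may contribute, because the depth of wild type over ddcc dry seed was 0.860 times as high in the quartile of 100 kb units with the most CHH methylation as in that with the least. On sites covered in both libraries the dry seed difference was -3.13 points, of which the spread of reads over sites made up -3.51 (-3.96 to -2.98) and the levels within sites 0.378 (-0.0263 to 0.853). Over windows above 50% in leaf the median dry seed difference was 3.17 points. That is above -1, the preset bound against a lower CG level at the same loci, so the preset test went against it. A lower CG level is still left open as a part over the whole genome, a departure from that test. The only ground is that the interval of the levels within sites, -0.0263 to 0.853, included 0. Their estimate of 0.378 points lay above 0, so the values show no net lowering. The quartiles over windows, -2.75 to 7.66, describe spread between windows and do not bear on a net difference. In the pericentromere a lower CG level does not account for the dry seed difference. The levels within sites made up 2.89 points there (1.502 to 4.34), against 1.46 with an interval that included 0 in postmature-green seed. In arms it may explain a small part, because the levels within sites made up -0.485 points there (-0.553 to -0.428) against -1.65 for the spread of reads, while the median over arm windows, -1.04 points, lay between the bounds of -1 and -2 set for the test.

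The CHG and CHH reads left in ddcc were weighed next. With sites above 3 times the median depth left out, the listed ddcc CHG level was 0.0766% in postmature-green seed, 0.0364% in dry seed and 0.0110% in leaf. The CHH level was 0.0533, 0.0104 and 0.00644% in the same order. A part of these reads thus lay at sites of high depth, and the comparisons of pericentromere with arm below kept such sites. Wild type DNA had a preset test on windows without CG methylation in ddcc leaf, where ddcc dry seed had a CG level of 5.20% after the arm CHH level was subtracted, more than the share of 0.828% needed, so this test alone would allow it; the stretch at DRM1 argues against it, because at that share 189 of its cytosines would be listed in ddcc dry seed and 0 were. Incomplete conversion alone would leave pericentromere and arm alike, but restored CHG was higher in the pericentromere by 0.225 points in postmature-green seed, 0.245 in dry seed and 0.0691 in leaf. For CHH the excess was at most 0.0294 points, within the bound of 0.05. Yet the counting intervals of arm and pericentromere did not overlap in any ddcc library, as with 0.115 to 0.116% against 0.143 to 0.144% in dry seed. The equality within counting intervals that this cause required was thus not met either, and it stays open for CHH. Conversion that fails beside a methylated CG may explain a part of the CCG reads. In the pericentromere, CCG sites beside a methylated CG were 8.49 times as high as beside an unmethylated CG in dry seed. The ratio was 4.94 in postmature-green seed and 3.68 in leaf, and 2.03 to 3.24 in arms. It cannot separate failed conversion from methylation, since wild type dry seed had 29.4 against 0.664% in the pericentromere. Beside a methylated CG, ddcc CCG was still higher in the pericentromere than in arms. It was 1.14 against 0.346% in dry seed, 1.22 against 0.534% in postmature-green seed and 0.392 against 0.205% in leaf. A methylated neighbour alone thus does not account for the difference between these regions. It does not account for the CAG and CTG sites of dry seed. They were 1.80 times as high in the pericentromere as in arms, against a preset bound of 1.5. Those of postmature-green seed (1.26) and leaf (1.20) stayed under the bound, so this cause stays open there. Yet the counting intervals of arm and pericentromere did not overlap in either library, as with 0.339 to 0.341% against 0.427 to 0.431% in postmature-green seed. In points, the excess was 0.0888 in postmature-green seed, 0.108 in dry seed and 0.0246 in leaf. The arm level was lower in dry seed, at 0.134%, which raises its ratio. What left the reads in dry seed stays open too.

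The CG windows that differ between ddcc and wild type were weighed last. Chance in the 2 libraries drawn is unlikely to account for them, because 45.5% of the leaf windows were called in the same direction in dry seed. That share lay between the preset bounds of 10 and 50%, so neither bound was reached, and the reading rests on 709 shared windows against 4.87 for independent lists, a comparison chosen afterwards. A loss of CG methylation that follows the loss of non-CG methylation cannot be told apart from other causes: 83.0% of the windows lower in ddcc dry seed had a wild type CHG level of at least 20%, but so had 58.4% of the tested windows with CG methylation, far over the background assumed for the test. Genetic differences between the ddcc and wild type lines stay open and were not tested.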

How the results depend on the processing

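The setting that restores absent sites was chosen after the data were seen; all other settings were planned. The labels carry no replicate numbers, so no replicate block could be fitted, and no result comes from a replicated test. Wild type and ddcc could have been paired by tissue across the 6 libraries, which was neither planned nor run. Of the alternative values of level differences that answer a comparison, 335 kept direction and side of the threshold, 11 reversed, 4 were weaker and 1 was stronger. Window counts stayed within 1.5 times in 66 cases and moved further in 42, gene counts in 61 and 3. Of the named genes' values, 940 kept their call and direction, 13 became weaker, 5 stronger and 1 reversed. The loss of CHG and CHH in ddcc and the higher CHH of wild type seeds kept their direction under every setting run. The depth limits small levels, since a site needs 2 methylated reads to be listed as methylated, and the minimum of 1 read equals the files' own minimum of 2. The cause was not tested for any change below, except that window length, flank length and size thresholds set how many windows or genes can be called.

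With the mean of site levels, the CG difference between ddcc and wild type was 0.580 points in postmature-green seed, 0.0581 points in dry seed (-0.194 to 0.279) and -0.147 points in leaf. In wild type CG it was 0.913 for postmature-green seed minus leaf, 0.707 for dry seed minus leaf and -0.206 for dry minus postmature-green seed, all reversed. For wild type CHG, dry minus postmature-green seed was -0.639, now apart from 0, and the same minus that in ddcc was -0.602, reversed. With sites covered in all 6 libraries, ddcc CG reversed to -0.489 for postmature-green seed minus leaf, -0.0543 for dry seed minus leaf and 0.435 for dry minus postmature-green seed. Wild type CHG became 0.329 for postmature-green seed minus leaf, with an interval that included 0, and 0.291 for dry minus postmature-green seed, reversed. The excess of the former over ddcc became 0.244 (-0.121 to 0.750), and with absent sites restored 0.148 (-0.132 to 0.532). With absent sites restored, ddcc CG reversed to -0.281, -0.0827 and 0.198 for the same 3 pairs, and wild type CHG for dry minus postmature-green seed to 0.174. In the pericentromere with absent sites restored, that CHG difference reversed to 0.467 and its excess over ddcc to 0.637. In arms with absent sites restored, dry minus postmature-green seed reversed to 0.251 for ddcc CG, -0.0429 for wild type CHG and -0.0813 for wild type CHH. With the housekeeping CHH level subtracted, ddcc dry minus postmature-green seed was -0.000293 for CHG and -0.00416 for CHH, with intervals that included 0.

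Window counts are given for ddcc against wild type in postmature-green seed, dry seed and leaf, then for wild type dry seed against leaf. With thresholds of 60, 40 and 20 points, CG had 286, 236, 504 and 1 called windows and CHH 13877, 15154, 398 and 2698, while CHG had 19716 in leaf and 141 between wild type dry seed and leaf. The 1 remaining CG window is among those lower in dry seed. With 20, 10 and 5 points, CG had 8144, 7521, 7691 and 3554, CHG 31442 between wild type dry seed and leaf, and CHH 32579 in leaf and 46068 between wild type dry seed and leaf. Windows of 200 bp gave 5450, 4971, 6991 and 769 for CG, 83504, 85297, 78129 and 13534 for CHG, and 107433, 109507, 36481 and 59968 for CHH. Windows of 1000 bp gave 283, 250, 391 and 23 for CG, 22496, 22545, 20785 and 1677 for CHG, and 20825, 21401, 6894 and 9921 for CHH. The CG calls of ddcc against wild type split into 33, 28 and 42 higher and 253, 208 and 462 lower at 60 points, into 4091, 3441 and 2701 higher and 4053, 4080 and 4990 lower at 20 points, and into 2287, 2061 and 2442 higher and 3163, 2910 and 4549 lower in windows of 200 bp. With counts divided by 4, CHG had 4132 between wild type postmature-green seed and leaf and 2867 between wild type dry seed and leaf. Between wild type dry and postmature-green seed, CHH then had 0 higher and 1 lower and CHG 0, and at thresholds of 60, 40 and 20 points CHH had 8 higher. Restoration gave 81 genes with lower flanking CHH in ddcc leaf. For CHH in wild type postmature-green seed and dry seed above leaf it gave 192 and 226 flanks and 278 and 290 bodies. Flanks of 500 bp gave 102 genes for CHG between wild type dry seed and leaf, and flanks of 2 kb gave 8. At 500 bp the flanking CHG difference of AT5G44410 was 0.583 points, reversed.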

Other observations

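The comparisons of window sets and the scan for missing stretches in this part were chosen only after results were seen. The windows with more CHH in wild type dry seed than in leaf were followed through all 6 libraries. Their median CHH level was 19.4% in wild type postmature-green seed, 20.2% in dry seed and 6.88% in leaf, and 0 in each ddcc library. The medians given with the calls in the report differ, because those used sites covered in both libraries of that comparison, while these used sites covered in both genotypes of a tissue. Their median CHG level was also 0 in each ddcc library. CG methylation was kept in them, with medians of 91.4% in wild type dry seed, 85.4% in wild type leaf and 84.2% in ddcc dry seed.

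The 196 windows with less CG in wild type dry seed than in leaf had a different profile. Their median CG level in ddcc was 41.4% in postmature-green seed, 43.8% in dry seed and 58.8% in leaf. Their median CHH level in wild type was 8.10% in dry seed and 3.04% in leaf. The windows with less CHG in wild type dry seed than in leaf lay within 1 kb of a protein-coding gene in 58.4% of cases, with median CHG levels of 22.4% in dry seed and 48.4% in leaf. Both seed stages shared 119 of their 195 and 191 CG-lower windows testable in both comparisons, against 0.162 for independent lists and 0 in simulated libraries without a difference. The simulation called 0 windows in each comparison, so it leaves open how much the shared leaf library adds to such an overlap.

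A scan of the genome for at least 20 cytosines in a row that were unlisted in all 3 libraries of a genotype, with at least 80% listed in each library of the other, found 2 stretches missing in ddcc. These were the stretch at DRM1 and the gap in CMT2. It found 6 stretches missing in wild type, 4428 bp in all. The longest, of 4018 bp, ran on chromosome 4 from 5876261 to 5880278 over AT4G09250 and AT4G09255. It held only 49 cytosines listed in any library, against 3687 in the 10067 bp at DRM1. Few of its cytosines were thus listed in ddcc either, and the 4428 bp do not measure DNA missing in wild type. Another stretch ran on chromosome 1 from 23390130 to 23390280 in AT1G63080.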
